A study of Arabidopsis thaliana with 26 samples.

How the data were processed

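Whole seedlings of Arabidopsis thaliana Col-0 were grown for 7 days in continuous growth light of 60 µmol photons per m2 per s at 22 °C. Part of the plates then received high light of 1200 with a stated leaf temperature of 22 °C, the rest stayed in growth light, and both were sampled at 0.5, 6, 12, 24, 48 and 72 h. Recovery samples were taken after 14 h of growth light following 72 h of high light. RNA came from 25 pooled plants per sample, and 4 µg went into each stranded mRNA library for single-end sequencing.

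The deposited files hold counts per gene, 1 library per file, as whole numbers without normalization. Per the submitters' processing notes, TopHat2 2.1.1, HTSeq 0.6.0 and edgeR were used with the TAIR10 genome build, and their roles, settings, read filters and strand setting are not given in the sources used here. Each file lists 33602 gene IDs, of which 32835 matched the reference annotation (TAIR10.1), which supplied gene symbols and products only, so no coordinates were used. Genes with no count in any of the 26 libraries numbered 6664. Counts of paralogs and of overlapping or antisense genes are less certain than others, since read assignment rules were not stated.

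Totals ran from 13637677 to 29697279 counts. The floor for groups with no count was 3 counts over their 2 libraries. In 1 library, 3 counts equal 0.101 CPM (largest total) to 0.22 CPM (smallest). The top 10 genes took 5.05 to 8.69% of the counts of a library, and chloroplast genes 0.012 to 0.101%. Replicate libraries correlated across genes at r from 0.9953 to 0.9982. PR1 and other genes with 0 to 3 counts in a group are given as a lower bound or as a ratio with an exact Poisson interval.

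Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr by group with a minimum count of 10, which left 21449, and scaled by TMM factors between 0.924 and 1.09. A model with 1 mean per group was fitted to all libraries, with 13 residual degrees of freedom, a common dispersion of 0.00428 and a biological coefficient of variation of 6.5%. Comparisons used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic, and levels are CPM with TMM scaling.

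The comparisons were high light against growth light at each of 6 times, the differences between those effects for neighbouring times and for 0.5 and 72 h, recovery against 72 h high light and against 72 h growth light, and the change over time in growth light. The comparisons, gene lists, named genes and alternatives were chosen before the data were examined, except where the text says otherwise. The 27 gene lists hold 579 distinct genes, and 570 were tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the residuals, and by rotation (fry), each adjusted over the lists of a comparison. The other gene groups of the closing section were chosen after the values were seen.

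Named genes follow a rule. It takes, in each high light or recovery comparison, the 5 largest rises and 5 largest falls past the test with at least 5 CPM in the higher group and both libraries of a group above both of the other, up to 4 called members of each list, and 32 sentinel genes named whatever their value. Differences of effects are reported for lists and as gene counts, and single genes are given there with their values at both times. Principal components used log2 CPM with a prior count of 2.

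The method was tested on simulated data in which 200 of 21107 genes were changed, 50 at each fold. For high light at 0.5 h, 22, 82, 100 and 100% were recovered at 1.25, 1.5, 2 and 4-fold with 10 false calls. For recovery against growth light 24, 70, 94 and 100% were recovered with 5 false calls, and for the difference between 6 and 0.5 h 8, 50, 88 and 100% with 6. In this simulation most changes of 1.25-fold were missed. Far fewer genes changed in it than were called in the data, so these shares may not carry over to the data.

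Alternatives tried were DESeq2 median-ratio (RLE) and upper-quartile factors, no filter, at least 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald or likelihood ratio test, the replicate number as a block, only the groups of the comparison in the fit, all 12 growth light libraries as the control, an added 2-fold threshold, and each library left out in turn. Counts thinned to the smallest library were added after the data were seen. No sample was left out of the main results.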

Results

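The data are gene counts from 26 mRNA sequencing libraries of Arabidopsis thaliana Col-0 whole seedlings, grown for 7 days before treatment. The seedlings stood in continuous light, either growth light of 60 µmol photons per m2 per s or high light of 1200, for 0.5, 6, 12, 24, 48 or 72 h. Another group, recovery, had 72 h of high light and then 14 h of growth light. Each of the 13 groups has 2 libraries, and each library comes from 25 pooled plants. Total counts per library ran from 13637677 to 29697279. The 72 h libraries held 16994443 and 16132345 counts in growth light and 13637677 and 17162530 in high light, and the recovery libraries 15306362 and 16473600.

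Gene values below are log2 fold changes ± SE with n = 2 libraries per group, and levels are CPM, mean ± SD, with the treated group first. A gene is called higher or lower when its adjusted p is below 0.05 among 21449 tested genes. For the 27 gene lists fixed beforehand, a second count in parentheses is adjusted over the list alone where it differed from the count over all genes. Where given, the median of a list is over log2 fold changes and its adjusted p comes from a list test, which asks whether its genes moved more in one direction than all other genes did. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

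**Figure D1:**
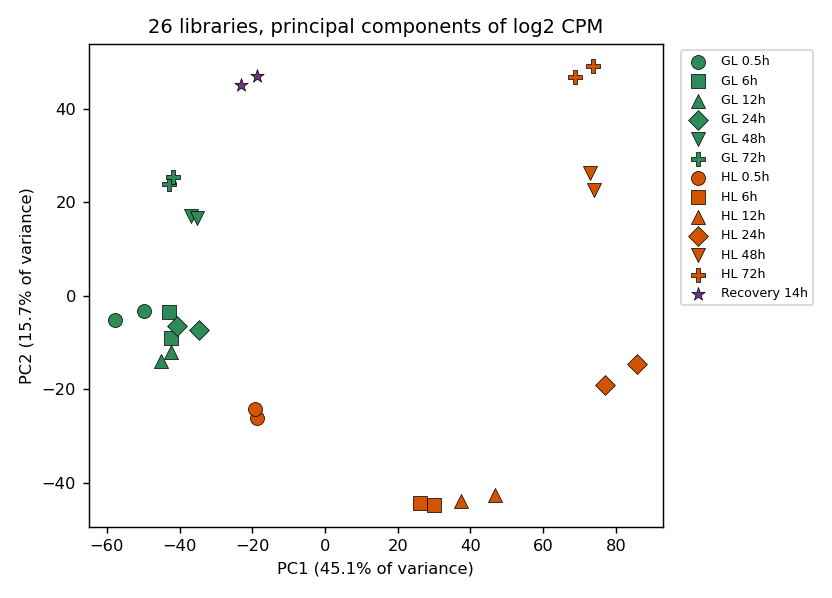
Principal components of log2 CPM in the 26 libraries, PC1 with 45.1% and PC2 with 16% of the variance, where color marks the light and marker shape the time. The recovery libraries lay at PC1 of -18.6 and -23.1 and PC2 of 47.1 and 45.1, close in PC2 to the 72 h high light libraries at 49.2 and 46.8.

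**Figure D2:**
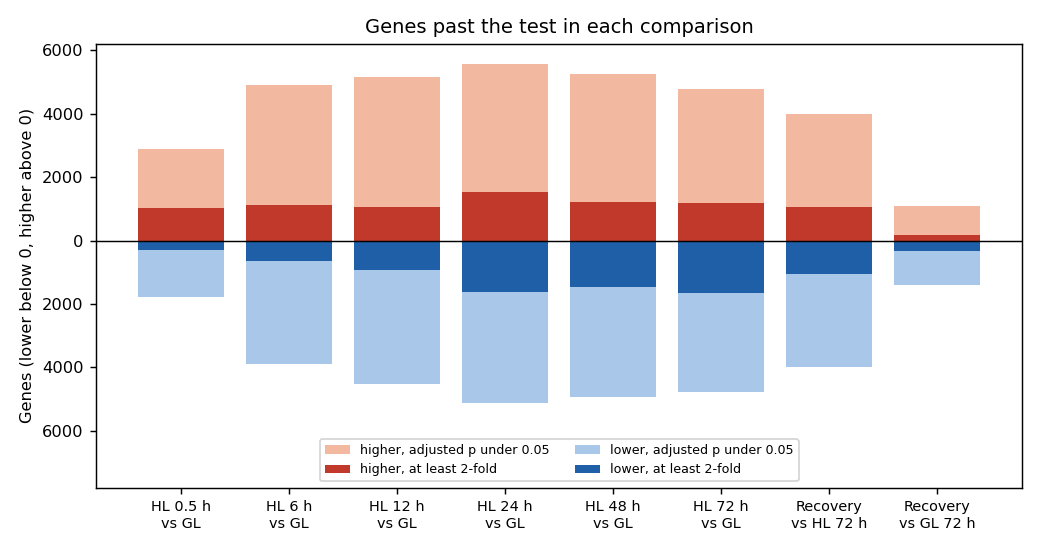
Number of genes called higher (up) or lower (down) in each comparison, with the part of at least 2-fold darker. At 24 h of high light the fit to all libraries called 5568 higher and 5117 lower, and 1079 were higher and 1410 lower in recovery against 72 h growth light.

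**Figure D3:**
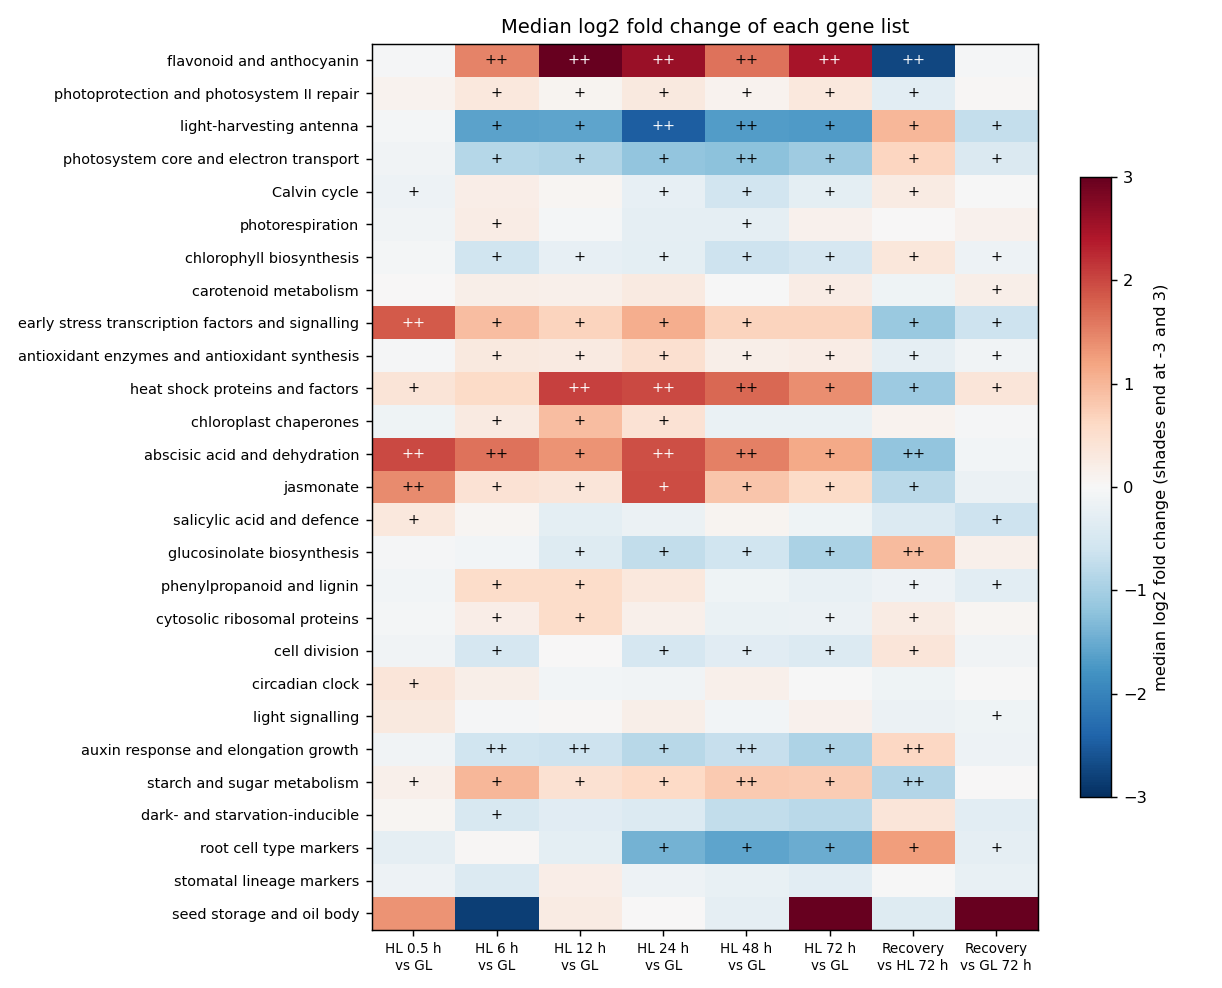
Median log2 fold change of the 27 gene lists (lines) in the 8 main comparisons (columns), with + for a list test call and ++ for one also called with an estimated correlation. With another scaling the sign flips only for medians near 0, which are carotenoid metabolism at 0.5 h, root cell type markers at 6 h, cell division at 12 h and seed storage and oil body at 24 h.

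The first comparison asks what high light changed within 0.5 h. Abscisic acid genes had the largest list median. NCED3 (AT3G14440), which encodes the enzyme that starts abscisic acid synthesis, rose by 4.81 ± 0.19 to 141 ± 11.5 CPM against 5 ± 0.563 CPM. Targets and feedback regulators of the hormone rose with it, with log2 fold changes of RD20 (AT2G33380) 6.10 ± 0.28, HAI1 (AT5G59220) 4.31 ± 0.29 and RD29A (AT5G52310) 3.28 ± 0.16. In the abscisic acid and dehydration list 26 of 29 genes were higher, 0 lower and 3 not past the test, median 1.99, adjusted p = 1.26e-64, adjusted p = 0.000664 with an estimated correlation. Stress transcription factor genes also rose, with ZAT10 (AT1G27730) 2.45 ± 0.15, WRKY40 (AT1G80840) 3.6 ± 0.28 and CBF2 (AT4G25470) 3.82 ± 0.24. In the early stress list 19 of 22 genes were higher, 0 lower and 3 not past the test, median 1.84, adjusted p = 3.94e-19, adjusted p = 0.00626 with an estimated correlation.

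Among jasmonate genes, the repressor gene JAZ1 (AT1G19180) 2.01 ± 0.14 and the lipoxygenase gene LOX4 (AT1G72520) 3.67 ± 0.21 rose, whereas LOX2 (AT3G45140) -0.01 ± 0.20, adjusted p = 0.978, did not pass the test. In the jasmonate list 15 of 23 genes were higher, 0 lower and 8 not past the test (16 and 0 adjusted over the list alone), median 1.41, adjusted p = 3.83e-15, adjusted p = 0.0392 with an estimated correlation. In the salicylic acid and defence list 8 of 21 genes were higher, 0 lower and 13 not past the test (9 and 1 adjusted over the list alone), median 0.31, with CBP60G (AT5G26920) 1.75 ± 0.20. PR1 (AT2G14610) had no count in any of the 4 libraries. In the glucosinolate list 4 of 27 genes were higher, 5 lower and 18 not past the test, with CYP81F2 (AT5G57220) 2.95 ± 0.27 and MYB51 (AT1G18570) 1.34 ± 0.12 up and MYB28 (AT5G61420) -0.66 ± 0.07 down.

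Few photosynthesis genes moved at 0.5 h. In the light-harvesting antenna list 1 of 21 genes were higher, 0 lower and 20 not past the test, and the riser was LHCB7 (AT1G76570) 0.88 ± 0.08. The photosystem core list had 0 of 30 higher, 4 lower and 26 not past the test, and the Calvin cycle 0 of 21 higher, 3 lower and 18 not past the test, median -0.16. Chlorophyll synthesis had 0 of 22 higher, 3 lower and 19 not past the test, and photorespiration 0 of 12 past the test. Genes of the early light-induced chlorophyll-binding proteins rose, with ELIP1 (AT3G22840) 2.14 ± 0.12 and ELIP2 (AT4G14690) 1.86 ± 0.17. ELIP1 was at 141 ± 18.6 CPM against 32 ± 0.639 CPM. The photoprotection list had 5 of 21 higher, 0 lower and 16 not past the test, and PSBS (AT1G44575) 0.02 ± 0.08, adjusted p = 0.928, was not past the test. In the carotenoid list 3 of 15 genes were higher, 1 lower and 11 not past the test, and the carotenoid cleavage gene CCD4 (AT4G19170) -1.50 ± 0.17 fell.

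In the flavonoid list 5 of 25 genes were higher, 0 lower and 20 not past the test, with a median of -0.04 and a mean of 0.17 that differ in sign. The regulator gene MYB12 (AT2G47460) 1.3 ± 0.17 rose, while CHS (AT5G13930) -0.26 ± 0.13, adjusted p = 0.184, the gene of the entry enzyme, did not pass. Heat shock factor genes HSFA2 (AT2G26150) 3.04 ± 0.44 and HSFA3 (AT5G03720) 2.01 ± 0.23 and the disaggregase gene HSP101 (AT1G74310) 0.74 ± 0.16 rose. In the heat shock list 10 of 28 genes were higher, 0 lower and 18 not past the test (10 and 1 adjusted over the list alone), median 0.39. In the clock list 11 of 20 genes were higher, 0 lower and 9 not past the test (11 and 1 adjusted over the list alone), median 0.37, with PRR9 (AT2G46790) 2.76 ± 0.17 and RVE6 (AT5G52660) 1.34 ± 0.09. Light signalling had 12 of 27 higher, 7 lower and 8 not past the test (14 and 9 adjusted over the list alone), with BBX32 (AT3G21150) 2.85 ± 0.12 and HY5 (AT5G11260) 1.13 ± 0.10 and PIF1 (AT2G20180) -1.69 ± 0.13. The sugar phosphate transporter gene GPT2 (AT1G61800) 5.24 ± 0.45 rose. In the starch and sugar list 6 of 20 genes were higher, 0 lower and 14 not past the test, median 0.16.

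In the antioxidant list 5 of 40 genes were higher, 1 lower and 34 not past the test, with APX1 (AT1G07890) -0.08 ± 0.12, adjusted p = 0.75, and a median of -0.04 and a mean of 0.08 that differ in sign. Phenylpropanoid genes had 1 of 17 higher, 4 lower and 12 not past the test, with PAL3 (AT5G04230) -1.04 ± 0.12, and cell division 1 of 25 higher, 3 lower and 21 not past the test (0 and 0 adjusted over the list alone). Root cell type markers had 0 of 24 higher, 7 lower and 17 not past the test, and auxin response 4 of 26 higher, 6 lower and 16 not past the test. Dark-inducible genes had 2 of 10 higher, 1 lower and 7 not past the test, and chloroplast chaperones 1 of 10 higher, 0 lower and 9 not past the test. For cytosolic ribosomal proteins 0 of 25 genes were past the test, for stomatal lineage markers 0 of 8 genes were past the test, and for seed storage genes 0 of 4 genes were past the test.

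Over all genes 2892 were higher, 1779 lower and 16778 not past the test, and 1017 and 315 of them changed at least 2-fold. By the list test, 7 lists upward and 1 downward were called. Of these, 3 stayed with an estimated correlation, and the rest had adjusted p from 0.0722 to 0.926 with an estimated correlation. The largest rises included AT4G28140 7.63 ± 0.33 and PUB19 (AT1G60190) 6.37 ± 0.20, genes of a DNA-binding protein and a ubiquitin ligase, and the largest falls OFP16 (AT2G32100) -3.85 ± 0.25 and BBX14 (AT1G68520) -3.22 ± 0.10. The test was edgeR's quasi-likelihood test on all 26 libraries, as in every comparison here. With upper-quartile scaling the split was 2583 higher and 2393 lower, and with only the groups of this comparison in the fit 2984 genes were called.

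The 6 h comparison asks which slower responses had begun. Antenna genes fell, among them LHCB1.4 (AT2G34430) -6.46 ± 0.24, LHCB2.2 (AT2G05070) -2.46 ± 0.19 and LHCB4.2 (AT3G08940) -2.72 ± 0.12, which encode chlorophyll-binding proteins of photosystem II. LHCB2.2 was at 261 ± 7.38 CPM against 1430 ± 77.4 CPM. In the antenna list 2 of 21 genes were higher, 17 lower and 2 not past the test, median -1.60, adjusted p = 7.87e-23, adjusted p = 0.0638 with an estimated correlation, and the risers were LHCB4.3 (AT2G40100) 1.52 ± 0.12 and LHCB7 1.49 ± 0.08. Reads are hard to assign between the LHCB1 and LHCB2 paralogs, so single copies are less certain than the list. In the photosystem core list 1 of 30 genes were higher, 25 lower and 4 not past the test, median -0.85, with PSAD2 (AT1G03130) -1.89 ± 0.10 and PETE1 (AT1G76100) -1.71 ± 0.08. In the chlorophyll list 1 of 22 genes were higher, 16 lower and 5 not past the test (1 and 17 adjusted over the list alone), median -0.60, with PORB (AT4G27440) -1.51 ± 0.12 and CAO (AT1G44446) -1.46 ± 0.08.

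Flavonoid genes rose, with the anthocyanin regulators PAP1 (AT1G56650) 2.79 ± 0.19 and PAP2 (AT1G66390) 6.23 ± 0.29 and the enzyme genes CHS 1.54 ± 0.14 and DFR (AT5G42800) 1.16 ± 0.20. In that list 23 of 25 genes were higher, 0 lower and 2 not past the test, median 1.5, adjusted p = 8.1e-22, adjusted p = 0.0354 with an estimated correlation. ELIP1 reached 1020 ± 27.2 CPM against 28.7 ± 1.36 CPM, the photosystem II protease gene FTSH8 (AT1G06430) 1.70 ± 0.10 rose, and so did PSBS 0.79 ± 0.08. In the photoprotection list 12 of 21 genes were higher, 3 lower and 6 not past the test, median 0.32. In the antioxidant list 21 of 40 genes were higher, 3 lower and 16 not past the test (22 and 3 adjusted over the list alone), median 0.30, with APX1 1.95 ± 0.13 and GPX7 (AT4G31870) 3.0 ± 0.14. In the phenylpropanoid list 11 of 17 genes were higher, 1 lower and 5 not past the test (12 and 2 adjusted over the list alone), median 0.56, with 4CL3 (AT1G65060) 1.53 ± 0.12 and PAL1 (AT2G37040) 0.98 ± 0.11 against PAL3 -1.41 ± 0.12.

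Abscisic acid genes stayed high, with RD29B (AT5G52300) 4.39 ± 0.71, HAI1 3.97 ± 0.27 and NCED3 3.37 ± 0.19. In that list 27 of 29 genes were higher, 0 lower and 2 not past the test (28 and 0 adjusted over the list alone), median 1.62, adjusted p = 2.92e-25, adjusted p = 0.0354 with an estimated correlation. The early stress list had 12 of 22 higher, 0 lower and 10 not past the test (13 and 0 adjusted over the list alone), median 0.92 (0.84 with empty groups set to the floor). Defence genes split into 3 of 21 higher, 3 lower and 15 not past the test, with PR5 (AT1G75040) 2.50 ± 0.15 and ICS1 (AT1G74710) -1.21 ± 0.13. The heat shock list had 11 of 28 higher, 3 lower and 14 not past the test (12 and 3 adjusted over the list alone), median 0.58, and HSP101 -0.25 ± 0.16, adjusted p = 0.223, was not past the test.

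Cell division genes fell, with CDC20.1 (AT4G33270) -0.90 ± 0.12 and CYCB1;2 (AT5G06150) -0.86 ± 0.11. In that list 0 of 25 genes were higher, 17 lower and 8 not past the test, median -0.50. In the auxin and elongation list 1 of 26 genes were higher, 14 lower and 11 not past the test (2 and 15 adjusted over the list alone), median -0.61, adjusted p = 1.33e-05, adjusted p = 0.0354 with an estimated correlation, with EXPA8 (AT2G40610) -4.01 ± 0.18 and SAUR20 (AT5G18020) -2.27 ± 0.21. Starch and sugar genes rose, with GPT2 7.41 ± 0.24 and BAM5 (AT4G15210) 6.25 ± 0.47. In that list 16 of 20 genes were higher, 2 lower and 2 not past the test, median 1.01. In the dark-inducible list 1 of 10 genes were higher, 5 lower and 4 not past the test (1 and 6 adjusted over the list alone), median -0.48, with DIN10 (AT5G20250) -1.68 ± 0.24 and the opposite mover DIN9 (AT1G67070) 0.75 ± 0.13. Stomatal lineage genes had 0 of 8 higher, 5 lower and 3 not past the test, median -0.41. Light signalling had 11 of 27 higher, 11 lower and 5 not past the test (11 and 12 adjusted over the list alone), with PIF4 (AT2G43010) -1.79 ± 0.16 and GLK2 (AT5G44190) -1.30 ± 0.10.

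Over all genes 4914 were higher, 3909 lower and 12626 not past the test, with 1128 and 643 at least 2-fold. With upper-quartile scaling the split became 4348 higher and 4619 lower. Called by the list test were 11 lists upward and 6 downward. The number that stayed with an estimated correlation was 3, and the others had adjusted p from 0.0638 to 0.645 with an estimated correlation. The cinnamyl alcohol dehydrogenase gene ELI3-2 (AT4G37990) had no count in growth light and was at least 268-fold higher, a floor that, like the intervals for other rare genes, covers counting error only. The lipid transfer protein gene LTP4 (AT5G59310) had a count ratio of 1350 (95% exact Poisson interval 461 to 6540). The root list median of 0.03 has the opposite sign to its test, which was not past.

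The 12 h comparison asks which later responses had joined. Flavonoid genes rose further, with 25 of 25 higher, median 3.6, adjusted p = 6.8e-68, adjusted p = 0.000618 with an estimated correlation. Late anthocyanin genes rose too, with DFR 5.23 ± 0.24, UGT79B1 (AT5G54060) 5.02 ± 0.24 and LDOX (AT4G22880) 4.92 ± 0.23, and CHS rose by 2.85 ± 0.14 to 3090 ± 49.1 CPM against 430 ± 53.2 CPM. Heat shock genes rose, with HSP17.6II (AT5G12020) 7.85 ± 0.44, HSFA2 4.02 ± 0.28 and HSP101 2.19 ± 0.14, the last at 76.1 ± 24.5 CPM against 16.7 ± 0.439 CPM. In that list 19 of 28 genes were higher, 1 lower and 8 not past the test, median 2.06 (1.90 with empty groups set to the floor), adjusted p = 1.17e-15, adjusted p = 0.0468 with an estimated correlation. Chloroplast chaperones had 8 of 10 higher, 0 lower and 2 not past the test, median 0.92 (0.81 with empty groups set to the floor), with HSP90.5 (AT2G04030) 1.47 ± 0.10.

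Ribosomal protein genes rose by small steps, with 25 of 25 higher, median 0.55, as in RPL10C (AT1G66580) 0.89 ± 0.10 and RPL38B (AT3G59540) 0.69 ± 0.08. Antenna genes stayed low, with LHCB2.2 -2.27 ± 0.19 and 2 of 21 higher, 18 lower and 1 not past the test, median -1.59, adjusted p = 5.55e-20, adjusted p = 0.0783 with an estimated correlation. In the antioxidant list 21 of 40 genes were higher, 4 lower and 15 not past the test (22 and 4 adjusted over the list alone), median 0.26, with GPX7 4.40 ± 0.16 and CAT3 (AT1G20620) -2.01 ± 0.16. In the starch and sugar list 13 of 20 genes were higher, 1 lower and 6 not past the test (13 and 2 adjusted over the list alone), median 0.46, with GPT2 5.97 ± 0.22 and BAM5 5.58 ± 0.33.

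Glucosinolate genes had 1 of 27 higher, 17 lower and 9 not past the test (1 and 18 adjusted over the list alone), median -0.38. Auxin and elongation genes had 1 of 26 higher, 16 lower and 9 not past the test (2 and 17 adjusted over the list alone), median -0.63, adjusted p = 3.58e-05, adjusted p = 0.0468 with an estimated correlation, with EXPA8 -4.43 ± 0.19. The chloroplast regulator genes GLK1 (AT2G20570) -1.52 ± 0.10 and GLK2 -1.53 ± 0.10 fell within light signalling, which had 9 of 27 higher, 11 lower and 7 not past the test (11 and 11 adjusted over the list alone). Carotenoid genes had 7 of 15 higher, 4 lower and 4 not past the test, with CCD4 -3.16 ± 0.20, and their median of 0.15 and mean of -0.06 differ in sign, as do 0.06 and -0.05 for the Calvin cycle. Over all genes 5163 were higher, 4528 lower and 11758 not past the test, with 1064 and 930 at least 2-fold. The list test called 11 lists upward and 5 downward. With an estimated correlation 3 of those calls stayed, and the rest had adjusted p from 0.0783 to 0.454 with an estimated correlation. Among the largest rises was HSP23.6 (AT4G25200), with a count ratio of 358 (95% exact Poisson interval 63.9 to 14200), and among the largest falls the ferric reductase gene FRO6 (AT5G49730) -4.34 ± 0.17.

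The 24 h comparison asks what a full day of high light did. In the fit to all libraries it has the most calls, whereas with only the groups of each comparison 48 h had 10658 and 72 h 10570 against 9581. Antenna genes had their lowest median, with LHCB1.4 -9.45 ± 0.29, LHCB2.2 -3.37 ± 0.20 and LHCB1.2 (AT1G29910) -3.59 ± 0.17. LHCB2.2 was at 80.1 ± 31.8 CPM against 830 ± 55.8 CPM. In the antenna list 2 of 21 genes were higher, 18 lower and 1 not past the test, median -2.48, adjusted p = 1.08e-28, adjusted p = 0.0365 with an estimated correlation, and LHCB4.3 2.09 ± 0.12 again rose against it. Photosystem core genes fell, with 30 of 30 lower, median -1.18, as in PSAD2 -2.78 ± 0.11 and PSAF (AT1G31330) -2.06 ± 0.11. The Calvin cycle had 0 of 21 higher, 11 lower and 10 not past the test, median -0.25, with RCA (AT2G39730) -0.96 ± 0.11, the gene of Rubisco activase.

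Flavonoid genes stayed high, with 25 of 25 higher, median 2.59, adjusted p = 3.7e-37, adjusted p = 0.00705 with an estimated correlation, as in F3'H (AT5G07990) 3.47 ± 0.16, PAP2 6.71 ± 0.22 and CHS 2.22 ± 0.14. In the antioxidant list 26 of 40 genes were higher, 6 lower and 8 not past the test, median 0.47, with GPX7 3.99 ± 0.14 and GR1 (AT3G24170) 1.64 ± 0.08 and CAT3 -2.12 ± 0.17. In the heat shock list 24 of 28 genes were higher, 1 lower and 3 not past the test, median 1.98, adjusted p = 1.3e-16, adjusted p = 0.026 with an estimated correlation, with HSP17.6A (AT5G12030) 7.24 ± 0.39, HSP17.6II 7.43 ± 0.46 and HSP101 2.08 ± 0.14. Jasmonate genes now included LOX2 2.1 ± 0.20 and VSP2 (AT5G24770) 4.63 ± 0.24, with LOX2 at 4720 ± 215 CPM against 1100 ± 135 CPM. In that list 19 of 23 genes were higher, 0 lower and 4 not past the test (20 and 0 adjusted over the list alone), median 1.95. The abscisic acid list had 27 of 29 higher, 0 lower and 2 not past the test, median 1.93, adjusted p = 3.98e-23, adjusted p = 0.026 with an estimated correlation, with RD20 5.32 ± 0.26. The early stress list had 10 of 22 higher, 0 lower and 12 not past the test, median 1.1, with ZAT12 (AT5G59820) 3.66 ± 0.22.

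Root markers fell, with PRP3 (AT3G62680) -2.48 ± 0.24, EXPA18 (AT1G62980) -2.30 ± 0.23 and XTH14 (AT4G25820) -2.24 ± 0.19 of root hairs. In that list 0 of 24 genes were higher, 17 lower and 7 not past the test, median -1.43. Cell division genes had 0 of 25 higher, 21 lower and 4 not past the test (0 and 23 adjusted over the list alone), median -0.51, with CDKB1;2 (AT2G38620) -0.79 ± 0.17 and PCNA1 (AT1G07370) -0.66 ± 0.09. Auxin genes had 3 of 26 higher, 16 lower and 7 not past the test, median -0.84, with EXPA8 -5.91 ± 0.26. Glucosinolate genes had 2 of 27 higher, 23 lower and 2 not past the test, median -0.73, with CYP79F1 (AT1G16410) -1.20 ± 0.16 and MYB29 (AT5G07690) -1.63 ± 0.17. Dark-inducible genes split into 3 of 10 higher, 5 lower and 2 not past the test, with DIN1 (AT4G35770) -4.10 ± 0.80 and DIN9 2.26 ± 0.12. The salicylic acid list median of -0.18 has the opposite sign to its test, which was not past.

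Over all genes 5568 were higher, 5117 lower and 10764 not past the test, with 1516 and 1610 at least 2-fold. By the list test, 9 lists upward and 8 downward were called. Of these, 4 stayed with an estimated correlation, and the rest had adjusted p from 0.0605 to 0.51 with an estimated correlation. The cellulose synthase-like gene CSLG2 (AT4G24000) was at least 236-fold higher, NATA1 (AT2G39030) had a count ratio of 1250 (95% exact Poisson interval 427 to 6060), and GASA6 (AT1G74670) -5.63 ± 0.24 was among the largest falls. With upper-quartile scaling the split became 4405 higher and 6161 lower, and the lower side was the larger also with no filter (5166 and 5282) and with only the groups of this comparison (4715 and 4866). High light 24 h replicate 2 had higher chloroplast, mitochondrial and ribosomal RNA shares than its partner, and 9532 genes were called without it.

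The 48 h comparison asks what lasted through a second day. Photosystem core genes fell, with 30 of 30 lower, median -1.23, adjusted p = 4.05e-39, adjusted p = 0.0339 with an estimated correlation, as in PSAN (AT5G64040) -2.31 ± 0.13 and PSAD2 -2.19 ± 0.10. The antenna list had 2 of 21 higher, 19 lower and 0 not past the test, median -1.68, adjusted p = 3.5e-23, adjusted p = 0.0433 with an estimated correlation, with LHCB1.4 -7.13 ± 0.25 and LHCB1.3 (AT1G29930) -2.36 ± 0.12 against LHCB4.3 1.60 ± 0.11. Carbon fixation genes were lower, with 0 of 21 higher, 18 lower and 3 not past the test, median -0.58, as in GAPA2 (AT1G12900) -1.18 ± 0.09 and RCA -1.06 ± 0.11. In the chlorophyll list 0 of 22 genes were higher, 19 lower and 3 not past the test, median -0.61, with HEMA1 (AT1G58290) -1.91 ± 0.16, PORB -2.15 ± 0.13 and CHLH (AT5G13630) -0.76 ± 0.11. HEMA1, the gene of the entry step, was at 76.6 ± 6.73 CPM against 287 ± 64.3 CPM.

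Starch and sugar genes were higher, with 17 of 20 higher, 2 lower and 1 not past the test, median 0.79, adjusted p = 1.18e-17, adjusted p = 0.0444 with an estimated correlation, led by GPT2 8.36 ± 0.21, BAM5 6.75 ± 0.25 and APL3 (AT4G39210) 3.95 ± 0.20. GPT2 was at 423 ± 2.92 CPM against 1.29 ± 0.336 CPM. Flavonoid genes had 24 of 25 higher, 0 lower and 1 not past the test, median 1.63, adjusted p = 6.87e-23, adjusted p = 0.03 with an estimated correlation, with CHS 1.31 ± 0.14 and PAP2 5.04 ± 0.26. The heat shock list had 25 of 28 higher, 1 lower and 2 not past the test, median 1.72, adjusted p = 4.55e-15, adjusted p = 0.03 with an estimated correlation, with HSP17.4 (AT3G46230) 5.19 ± 0.40 and HSP101 0.74 ± 0.15. Chloroplast chaperones moved apart, with 3 of 10 higher, 4 lower and 3 not past the test (3 and 5 adjusted over the list alone), where CLPB3 (AT5G15450) 1.54 ± 0.12 rose and CPN60B1 (AT1G55490) -0.57 ± 0.11 fell, and their median of -0.19 and mean of 0.20 differ in sign. The abscisic acid list had 24 of 29 higher, 0 lower and 5 not past the test, median 1.52, adjusted p = 4.23e-19, adjusted p = 0.03 with an estimated correlation.

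Root markers stayed low, with 1 of 24 higher, 17 lower and 6 not past the test, median -1.58, as in EXPA18 -2.47 ± 0.23 and XTH14 -2.38 ± 0.19. Auxin genes had 1 of 26 higher, 17 lower and 8 not past the test (1 and 18 adjusted over the list alone), median -0.68, adjusted p = 1.4e-06, adjusted p = 0.03 with an estimated correlation. Dark-inducible genes had 2 of 10 higher, 6 lower and 2 not past the test, median -0.74, with DIN10 -2.12 ± 0.24 and TPS8 (AT1G70290) -2.14 ± 0.13 against DIN2 (AT3G60140) 4.79 ± 0.31. Over all genes 5261 were higher, 4923 lower and 11265 not past the test, with 1217 and 1471 at least 2-fold. The lower side became the larger with upper-quartile factors (4774 and 5339), DESeq2 factors (5065 and 5073), no filter (4815 and 5055), only the groups of this comparison (5277 and 5381) and DESeq2 (4208 and 4389). Called by the list test were 8 lists upward and 9 downward. The number that stayed with an estimated correlation was 7, and the others had adjusted p from 0.0567 to 0.686 with an estimated correlation. CSLG2 had a count ratio of 1600 (95% exact Poisson interval 287 to 63200), CSLA01 (AT4G16590) 8.54 ± 0.43 was among the largest rises, and DOT3 (AT5G10250) -5.76 ± 0.40 among the largest falls.

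The 72 h comparison asks what state the seedlings had reached before recovery. Glucosinolate genes were lower, with 0 of 27 higher, 26 lower and 1 not past the test, median -0.94, including CYP79F1 -2.15 ± 0.17 and MAM1 (AT5G23010) -1.77 ± 0.16 of the methionine-derived branch. The antenna list had 2 of 21 higher, 17 lower and 2 not past the test, median -1.70, adjusted p = 3.88e-24, adjusted p = 0.0576 with an estimated correlation, with LHCB1.4 -9.41 ± 0.31 and LHCB2.2 -3.45 ± 0.20 and, upward, LHCB4.3 2.75 ± 0.12. The photosystem core had 0 of 30 higher, 27 lower and 3 not past the test (0 and 28 adjusted over the list alone), median -1.06, with PSAF -2.40 ± 0.11. In the chlorophyll list 0 of 22 genes were higher, 19 lower and 3 not past the test, median -0.51, with HEMA1 -2.56 ± 0.17 and PORB -2.64 ± 0.13. HEMA1 was at 50 ± 0.46 CPM against 294 ± 23.1 CPM.

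**Figure D4:**
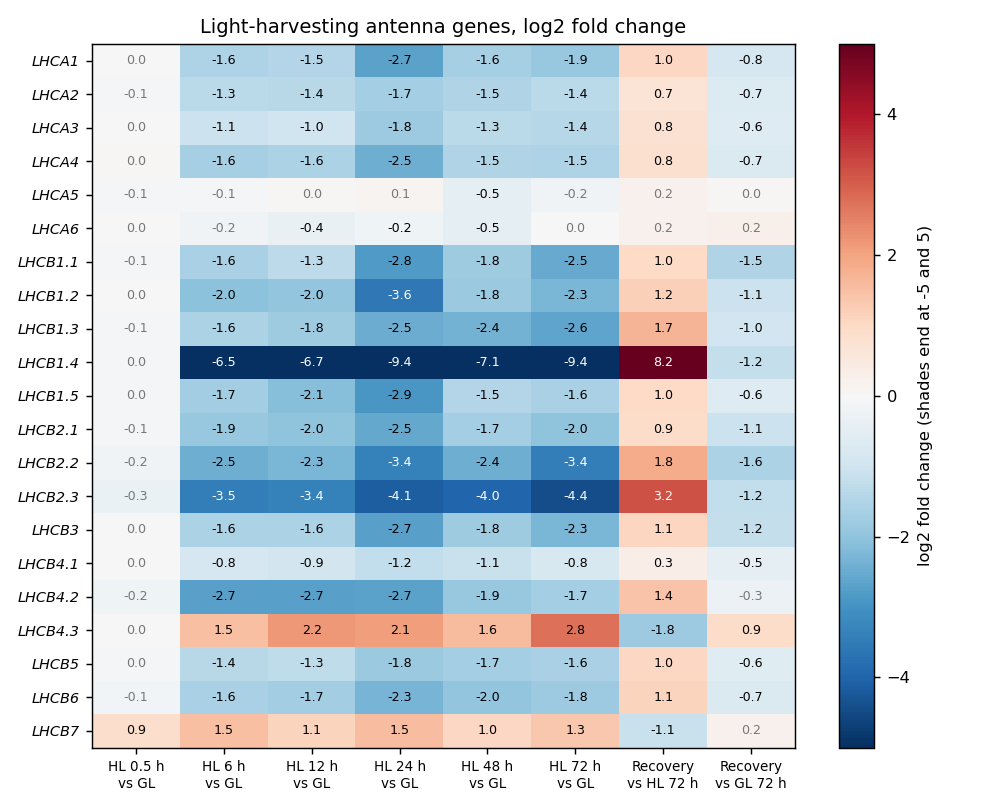
Log2 fold change of the 21 light-harvesting antenna genes (lines) in the 8 main comparisons (columns), with values not past the test in grey. Most genes fell from 6 h on, LHCB2.2 to -3.45 at 72 h, while LHCB4.3 rose to 2.75.

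The photoprotection list had 13 of 21 higher, 2 lower and 6 not past the test (14 and 2 adjusted over the list alone), median 0.33, with ELIP1 6.63 ± 0.14 and PSBS 1.0 ± 0.08. Flavonoid genes had 24 of 25 higher, 0 lower and 1 not past the test, median 2.47, adjusted p = 2.94e-40, adjusted p = 0.00559 with an estimated correlation, with F3'H 3.88 ± 0.17, DFR 3.3 ± 0.21 and CHS 2.06 ± 0.14. Carotenoid genes had 7 of 15 higher, 3 lower and 5 not past the test, median 0.21, with the hydroxylase gene BCH1 (AT4G25700) 1.58 ± 0.08 up and CCD4 -1.60 ± 0.18 down. Starch and sugar genes had 16 of 20 higher, 2 lower and 2 not past the test (17 and 2 adjusted over the list alone), median 0.75, with GPT2 8.87 ± 0.25. The heat shock list had 21 of 28 higher, 1 lower and 6 not past the test, median 1.39, with HSP17.8 (AT1G07400) 5.23 ± 0.29 and HSP101 0.80 ± 0.16. The abscisic acid list had 22 of 29 higher, 1 lower and 6 not past the test (23 and 1 adjusted over the list alone), median 1.15, with NCED3 1.21 ± 0.25. The jasmonate list had 12 of 23 higher, 0 lower and 11 not past the test, median 0.57, with VSP1 (AT5G24780) 4.94 ± 0.24 and LOX2 1.69 ± 0.20.

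Root markers had 0 of 24 higher, 18 lower and 6 not past the test (0 and 19 adjusted over the list alone), median -1.48, with LRX1 (AT1G12040) -3.38 ± 0.43 and PRP3 -3.24 ± 0.33. Auxin genes had 2 of 26 higher, 17 lower and 7 not past the test, median -0.93, with EXPA1 (AT1G69530) -1.91 ± 0.10. Cell division genes had 0 of 25 higher, 15 lower and 10 not past the test (0 and 18 adjusted over the list alone), median -0.41, with CDC20.2 (AT4G33260) -0.79 ± 0.11. Antioxidant genes had 20 of 40 higher, 9 lower and 11 not past the test (23 and 9 adjusted over the list alone), median 0.23, with DHAR1 (AT1G19570) 2.25 ± 0.12 against CAT3 -2.38 ± 0.17 and APX1 -0.49 ± 0.13. Dark-inducible genes had 2 of 10 higher, 7 lower and 1 not past the test, median -0.82, though DIN2 4.93 ± 0.33 rose.

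Seed storage genes had 1 of 4 higher, 0 lower and 3 not past the test (3 and 0 adjusted over the list alone), with a median of 3.78 (2.86 with empty groups set to the floor) that rests on empty groups. Over all genes 4780 were higher, 4787 lower and 11882 not past the test, with 1194 and 1669 at least 2-fold. The higher side was the larger with at least 1 CPM in 2 libraries (4784 and 4569) and with all 12 growth light libraries as the control (5551 and 5144). The list test called 8 lists upward and 9 downward. With an estimated correlation 1 of those calls stayed, and the rest had adjusted p from 0.0576 to 0.733 with an estimated correlation. The sucrose transporter gene SUC7 (AT1G66570) was at least 86.7-fold higher, HSP17.6A had a count ratio of 486 (95% exact Poisson interval 86.8 to 19200), and AT3G16670 -6.56 ± 0.37 was among the largest falls.

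**Figure D5:**
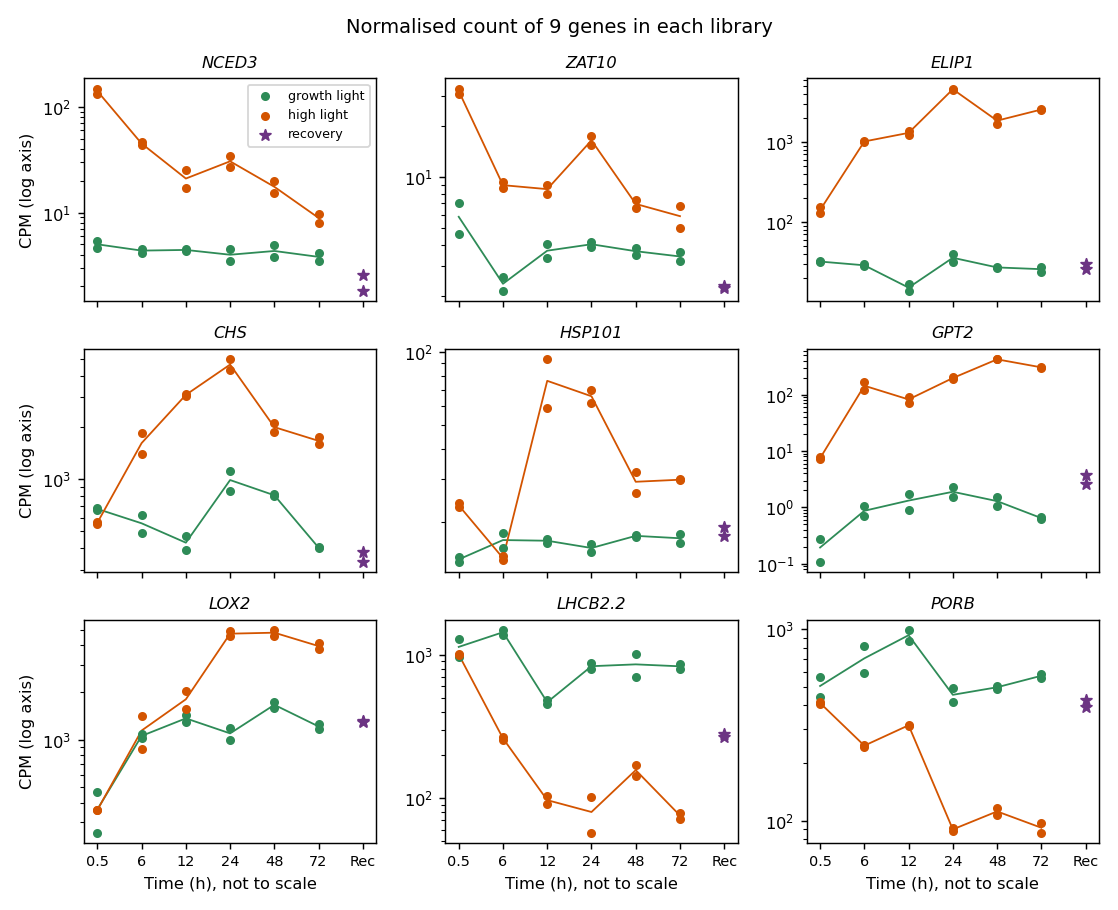
CPM on a log axis against hours for 9 genes, with points for libraries, lines for group means and a star for recovery. ELIP1, CHS and GPT2 rose in high light and LHCB2.2 and PORB fell, while NCED3 and ZAT10 peaked at 0.5 h.

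Across the 6 times, 17605 genes were called at 1 or more times. Higher at every time were 624 genes and lower 635, of which 140 and 91 changed at least 2-fold each time. Another 2314 genes were called in opposite directions at different times. Each also had a called difference between neighbouring times or between 0.5 and 72 h, which need not be the times of opposite sign. From 0.5 to 72 h, 344 genes went from higher to lower and 126 from lower to higher. Higher at both 48 and 72 h were 3628 genes and lower 3686, where 1172 and 1099 would overlap if independent. Higher at both 0.5 and 72 h were 1202 genes and lower 1054, where 644 and 397 would overlap if independent.

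The difference between the effects at 6 h and 0.5 h asks which responses are late and which early. No list kept its call with an estimated correlation here, so the counts speak for single genes. The antenna list had 2 of 21 higher, 17 lower and 2 not past the test, median -1.52, adjusted p = 1.16e-22, adjusted p = 0.124 with an estimated correlation. Photosystem core genes had 1 of 30 higher, 24 lower and 5 not past the test, median -0.77, and flavonoid genes 20 of 25 higher, 1 lower and 4 not past the test (22 and 1 adjusted over the list alone), median 1.51. The abscisic acid list had 4 of 29 higher, 14 lower and 11 not past the test (4 and 15 adjusted over the list alone), median -0.69, and the early stress list 0 of 22 higher, 7 lower and 15 not past the test (0 and 8 adjusted over the list alone), median -0.83. LHCB2.2 was -0.18 ± 0.18 at 0.5 h and -2.46 ± 0.19 at 6 h. NCED3 was 4.81 ± 0.19 at 0.5 h and 3.37 ± 0.19 at 6 h. By the list test, 9 lists upward and 12 downward were called. Of these, 0 stayed with an estimated correlation, and the rest had adjusted p from 0.124 to 0.438 with an estimated correlation. The effect on 6347 genes differed, 3166 upward and 3181 downward, and on 4171 with only the groups of this comparison in the fit. The larger side depends on the setting, as with at least 1 CPM in 2 libraries (3340 and 2984).

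The 6 and 12 h effects were compared to find what grew in between. The flavonoid list moved further up, with 17 of 25 higher, 0 lower and 8 not past the test (20 and 1 adjusted over the list alone), median 1.3, adjusted p = 4.32e-57, adjusted p = 0.0011 with an estimated correlation. DFR was 1.16 ± 0.20 at 6 h and 5.23 ± 0.24 at 12 h. The heat shock list moved up, with 16 of 28 higher, 1 lower and 11 not past the test, median 1.47, adjusted p = 3.25e-23, adjusted p = 0.00914 with an estimated correlation. HSP101 was -0.25 ± 0.16 at 6 h and 2.19 ± 0.14 at 12 h. Cell division genes had 10 of 25 higher, 0 lower and 15 not past the test (17 and 0 adjusted over the list alone), median 0.51, starch and sugar genes 0 of 20 higher, 9 lower and 11 not past the test (0 and 10 adjusted over the list alone), median -0.56, and neither list was called with an estimated correlation. Called by the list test were 9 lists upward and 6 downward. The number that stayed with an estimated correlation was 2, and the others had adjusted p from 0.263 to 0.681 with an estimated correlation. The effect on 2062 genes differed, 842 upward and 1220 downward, and on 1289 with only the groups of this comparison in the fit. The count was 1372 without growth light 6 h replicate 2, 1147 without high light 6 h replicate 2 and 1134 without high light 12 h replicate 2.

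The same was asked of 12 and 24 h. The jasmonate list had 16 of 23 higher, 0 lower and 7 not past the test, median 1.11. LOX2 was 0.40 ± 0.20 at 12 h and 2.1 ± 0.20 at 24 h. Root markers had 0 of 24 higher, 12 lower and 12 not past the test, median -1.23, flavonoid genes 0 of 25 higher, 16 lower and 9 not past the test (0 and 18 adjusted over the list alone), median -0.78, and antenna genes 1 of 21 higher, 12 lower and 8 not past the test (1 and 14 adjusted over the list alone), median -0.70, adjusted p = 6.48e-11, adjusted p = 0.268 with an estimated correlation. The list test called 7 lists upward and 11 downward. With an estimated correlation 0 of those calls stayed, and the rest had adjusted p from 0.104 to 0.539 with an estimated correlation. The effect on 3165 genes differed, 1539 upward and 1626 downward, or 1169 and 2251 with upper-quartile scaling and 1845 and 1497 with at least 1 CPM in 2 libraries. The count was 1969 without growth light 12 h replicate 2, 1892 without growth light 24 h replicate 1, 1618 without high light 12 h replicate 2 and 1792 without high light 24 h replicate 1.

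From 24 to 48 h the antenna list had 10 of 21 higher, 3 lower and 8 not past the test (12 and 3 adjusted over the list alone), median 0.48, adjusted p = 6.34e-07, adjusted p = 0.507 with an estimated correlation. LHCB2.2 was -3.37 ± 0.20 at 24 h and -2.45 ± 0.19 at 48 h. Flavonoid genes had 0 of 25 higher, 12 lower and 13 not past the test (0 and 17 adjusted over the list alone), median -0.75, and photoprotection genes 1 of 21 higher, 10 lower and 10 not past the test (3 and 12 adjusted over the list alone), median -0.39. By the list test, 3 lists upward and 12 downward were called. Of these, 0 stayed with an estimated correlation, and the rest had adjusted p from 0.507 to 0.691 with an estimated correlation. The effect on 2648 genes differed, 1072 upward and 1576 downward, or 1447 and 1269 with upper-quartile scaling, which makes the upward side the larger. The count was 1638 without growth light 48 h replicate 2, 1758 without high light 24 h replicate 1 and 1563 without high light 48 h replicate 1.

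From 48 to 72 h few effects differed in the fit to all libraries. Flavonoid genes had 9 of 25 higher, 0 lower and 16 not past the test (20 and 0 adjusted over the list alone), median 0.75. DFR was 1.98 ± 0.20 at 48 h and 3.3 ± 0.21 at 72 h. In the glucosinolate list 0 of 27 genes were higher, 0 lower and 27 not past the test (0 and 17 adjusted over the list alone), median -0.44, adjusted p = 2.15e-13, adjusted p = 0.143 with an estimated correlation. CYP79F1 was -1.33 ± 0.16 at 48 h and -2.15 ± 0.17 at 72 h. Called by the list test were 8 lists upward and 5 downward. The number that stayed with an estimated correlation was 0, and the others had adjusted p from 0.0794 to 0.683 with an estimated correlation. The effect on 244 genes differed, 138 upward and 106 downward, and on 1277 with only the groups of this comparison in the fit and 680 with no filter, 297 upward and 383 downward. That count depended on every library. It was 105 without growth light 48 h replicate 1, 60 without growth light 48 h replicate 2, 58 without high light 48 h replicate 1 and 83 without high light 48 h replicate 2. It was 41 without growth light 72 h replicate 1, 26 without growth light 72 h replicate 2, 15 without high light 72 h replicate 1 and 60 without high light 72 h replicate 2.

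The difference between 72 h and 0.5 h sets the late state against the first response. The flavonoid list moved up, with 21 of 25 higher, 0 lower and 4 not past the test, median 2.06, adjusted p = 6.59e-35, adjusted p = 0.0113 with an estimated correlation. The antenna list had 2 of 21 higher, 17 lower and 2 not past the test, median -1.60, adjusted p = 1.15e-25, adjusted p = 0.0788 with an estimated correlation. Glucosinolate genes had 0 of 27 higher, 23 lower and 4 not past the test, median -0.99, and abscisic acid genes 1 of 29 higher, 17 lower and 11 not past the test (1 and 18 adjusted over the list alone), median -0.70. NCED3 was 4.81 ± 0.19 at 0.5 h and 1.21 ± 0.25 at 72 h. ZAT10 was 2.45 ± 0.15 at 0.5 h and 0.77 ± 0.20 at 72 h. The list test called 5 lists upward and 11 downward. With an estimated correlation 1 of those calls stayed, and the rest had adjusted p from 0.0788 to 0.674 with an estimated correlation. The effect on 6565 genes differed, 2807 upward and 3758 downward.

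In growth light alone 9917 genes changed over the 6 times, by the quasi-likelihood test over all times. Of them, 1277 changed at least 2-fold from the 0.5 h samples, a measure that leaves out changes between later times. Called were 18 of 20 clock, 26 of 27 glucosinolate, 19 of 21 antenna, 20 of 25 flavonoid and 5 of 28 heat shock genes, with a median largest log2 change of 1.05 in the clock list. DESeq2 called 6108 genes in the same comparison. Each high light time is set against its own growth light time, which takes this change into account.

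Recovery against 72 h high light asks what moved back within 14 h of growth light. Flavonoid genes fell, with PAP2 -6.42 ± 0.36, F3'H -4.08 ± 0.17 and DFR -3.59 ± 0.22. In that list 0 of 25 genes were higher, 23 lower and 2 not past the test (0 and 25 adjusted over the list alone), median -2.74, adjusted p = 2.18e-53, adjusted p = 0.00154 with an estimated correlation. ELIP1 was at 27.6 ± 2.72 CPM against 2550 ± 91.6 CPM. In the photoprotection list 1 of 21 genes were higher, 14 lower and 6 not past the test, median -0.31. Antenna genes rose, with LHCB1.4 8.23 ± 0.31 and LHCB2.2 1.85 ± 0.19 and 17 of 21 higher, 2 lower and 2 not past the test (19 and 2 adjusted over the list alone), median 1.01, adjusted p = 4.59e-13, adjusted p = 0.134 with an estimated correlation, while LHCB4.3 -1.82 ± 0.11 fell. The photosystem core had 26 of 30 higher, 0 lower and 4 not past the test (27 and 0 adjusted over the list alone), median 0.64. Chlorophyll synthesis had 14 of 22 higher, 2 lower and 6 not past the test, median 0.34, with PORB 2.16 ± 0.13.

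Starch and sugar genes fell, with GPT2 -6.60 ± 0.20, BAM5 -6.90 ± 0.29 and APL3 -3.84 ± 0.20. In that list 2 of 20 genes were higher, 18 lower and 0 not past the test, median -0.89, adjusted p = 5.72e-22, adjusted p = 0.0391 with an estimated correlation. Glucosinolate genes rose, with CYP79F1 2.46 ± 0.17 and MAM1 2.13 ± 0.16 and 23 of 27 higher, 1 lower and 3 not past the test, median 0.95, adjusted p = 1.09e-21, adjusted p = 0.0467 with an estimated correlation. The abscisic acid list had 0 of 29 higher, 25 lower and 4 not past the test, median -1.19, adjusted p = 3.16e-18, adjusted p = 0.0391 with an estimated correlation, with COR15A (AT2G42540) -3.69 ± 0.24. The jasmonate list had 0 of 23 higher, 14 lower and 9 not past the test (0 and 15 adjusted over the list alone), median -0.81, with VSP1 -5.75 ± 0.26. The early stress list had 0 of 22 higher, 11 lower and 11 not past the test (0 and 13 adjusted over the list alone), median -1.11 (-0.97 with empty groups set to the floor). The heat shock list had 1 of 28 higher, 22 lower and 5 not past the test (1 and 23 adjusted over the list alone), median -1.09, with HSFA2 -2.41 ± 0.30.

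Growth genes rose, with EXPA8 5.86 ± 0.21 and EXPA1 2.29 ± 0.11. In the auxin list 13 of 26 genes were higher, 2 lower and 11 not past the test, median 0.62, adjusted p = 2.74e-05, adjusted p = 0.0391 with an estimated correlation, where GH3.3 (AT2G23170) -1.51 ± 0.21 fell. Root markers rose, with PRP3 2.70 ± 0.34 and LRX1 2.63 ± 0.47 and 17 of 24 higher, 0 lower and 7 not past the test (19 and 0 adjusted over the list alone), median 1.26. Ribosomal genes had 16 of 25 higher, 1 lower and 8 not past the test (21 and 1 adjusted over the list alone), median 0.24, with RPL23AB (AT3G55280) 0.44 ± 0.08. Stomatal lineage genes had 2 of 8 higher, 0 lower and 6 not past the test, and their median of -0.01 has the opposite sign to the test, which was not past.

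Over all genes 3982 were higher, 3979 lower and 13488 not past the test, with 1052 and 1044 at least 2-fold. The larger side depends on the setting, as with only the groups of this comparison (4256 and 4373). By the list test, 9 lists upward and 9 downward were called. Of these, 5 stayed with an estimated correlation, and the rest had adjusted p from 0.0972 to 0.583 with an estimated correlation. By the rule for named genes, with at least 5 CPM in the higher group, the largest fall was NUDT24 (AT5G19470) -7.23 ± 0.31, a nudix hydrolase gene. This comparison shares its 72 h high light libraries with the 72 h comparison, so opposite signs in both are partly built in. The extent of return was therefore taken from genes called at 48 h, whose libraries are not in the recovery comparisons.

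Of the 5261 genes higher at 48 h, the median log2 fold change was 0.462 at 72 h and 0.091 in recovery against growth light, and 560 were still higher and 142 lower, where 265 and 346 would be if independent. Of the 4923 lower genes, the median was -0.581 at 72 h and -0.134 in recovery, and 871 were still lower and 151 higher, where 324 and 248 would be if independent. The 72 h and recovery values share their growth light controls, so these medians are not independent of each other. For genes of at least 2-fold at 48 h the recovery medians were 0.184 and -0.448.

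Recovery against 72 h growth light asks what still differed after 14 h. Antenna genes were lower, with LHCB2.2 -1.60 ± 0.18 and LHCB1.1 (AT1G29920) -1.50 ± 0.15 and 1 of 21 higher, 16 lower and 4 not past the test (3 and 17 adjusted over the list alone), median -0.72, adjusted p = 2.59e-19, adjusted p = 0.238 with an estimated correlation, while LHCB4.3 0.92 ± 0.12 was higher. The photosystem core had 0 of 30 higher, 21 lower and 9 not past the test (1 and 23 adjusted over the list alone), median -0.42, with PSAF -1.31 ± 0.11 and PSAD2 -1.16 ± 0.10. Chlorophyll synthesis had 0 of 22 higher, 6 lower and 16 not past the test (0 and 10 adjusted over the list alone), median -0.16, with HEMA1 -2.66 ± 0.17 and CHLH -0.97 ± 0.11. HEMA1 was at 46.5 ± 6.08 CPM against 294 ± 23.1 CPM. Heat shock genes included HSP17.4 4.90 ± 0.59, HSP17.8 3.39 ± 0.34 and HSP90.1 (AT5G52640) 1.49 ± 0.17, with 7 of 28 higher, 1 lower and 20 not past the test (11 and 1 adjusted over the list alone), median 0.37, whereas HSP101 0.09 ± 0.17, adjusted p = 0.777, did not pass the test. Phenylpropanoid genes had 0 of 17 higher, 11 lower and 6 not past the test (0 and 13 adjusted over the list alone), median -0.31, with PAL2 (AT3G53260) -0.55 ± 0.11 and F5H (AT4G36220) -0.79 ± 0.10.

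In the flavonoid list 0 of 25 genes were past the test, over all genes or adjusted over the list alone, as in CHS -0.18 ± 0.13, adjusted p = 0.441. ELIP1 was at 0.11 ± 0.13, adjusted p = 0.671, and LOX2 at 0.10 ± 0.20, adjusted p = 0.791. Photoprotection had 2 of 21 higher, 0 lower and 19 not past the test, and the Calvin cycle 1 of 21 higher, 1 lower and 19 not past the test. Jasmonate had 0 of 23 higher, 2 lower and 21 not past the test, and abscisic acid 1 of 29 higher, 3 lower and 25 not past the test (2 and 3 adjusted over the list alone). Carotenoid genes had 2 of 15 higher, 2 lower and 11 not past the test (4 and 2 adjusted over the list alone), median 0.17, with BCH1 1.46 ± 0.08. Antioxidant genes had 5 of 40 higher, 10 lower and 25 not past the test (6 and 11 adjusted over the list alone), median -0.11, with FSD1 (AT4G25100) -3.22 ± 0.17 and APX1 -1.01 ± 0.13. FSD1, the gene of an iron superoxide dismutase, was at 45 ± 0.525 CPM against 420 ± 14.3 CPM.

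Early stress genes had 0 of 22 higher, 5 lower and 17 not past the test (0 and 6 adjusted over the list alone), median -0.61 (-0.59 with empty groups set to the floor). Defence genes had 1 of 21 higher, 4 lower and 16 not past the test (1 and 8 adjusted over the list alone), median -0.62. PR1 was lower, with a growth light over recovery count ratio of 46 (95% exact Poisson interval 15.4 to 226). Light signalling had 1 of 27 higher, 6 lower and 20 not past the test (2 and 7 adjusted over the list alone), median -0.12. The root list had 0 of 24 higher, 2 lower and 22 not past the test (0 and 1 adjusted over the list alone), median -0.28. The clock had 6 of 20 higher, 8 lower and 6 not past the test (7 and 9 adjusted over the list alone), with LHY (AT1G01060) at -0.75 ± 0.11. In the starch and sugar list 3 of 20 genes were higher, 2 lower and 15 not past the test (4 and 4 adjusted over the list alone), with GPT2 2.27 ± 0.44 still higher. Dark-inducible genes had 1 of 10 higher, 3 lower and 6 not past the test, with DIN2 3.81 ± 0.37, and a median of -0.32 and mean of 0.09 that differ in sign. Glucosinolate genes had 3 of 27 higher, 2 lower and 22 not past the test (5 and 4 adjusted over the list alone).

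Over all genes 1079 were higher, 1410 lower and 18960 not past the test, with 184 and 343 at least 2-fold. Called by the list test were 2 lists upward and 9 downward. The number that stayed with an estimated correlation was 0, and the others had adjusted p from 0.238 to 0.766 with an estimated correlation. Among genes with at least 5 CPM in the higher group, the largest rises were HSP17.6A, with a count ratio of 231 (95% exact Poisson interval 41 to 9160), and AT1G62420 6.39 ± 0.28, and the largest fall NEET (AT5G51720) -4.65 ± 0.60, an iron-sulfur cluster protein gene. The controls were 14 h younger than the recovery plants, since no growth light group of that age was used here. The count was 1233 without growth light 72 h replicate 1, 1039 without growth light 72 h replicate 2, 1054 without recovery replicate 1 and 1377 without recovery replicate 2. It was 4470 with only the groups of this comparison in the fit and 4411 against all 12 growth light libraries, 1718 of them shared.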

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

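The tests of leaf warming and of root share in this part were chosen only after the result was seen. The results here stand out because the effect of high light differed between times by a test of the difference itself. Effects differed for 6347 genes between 0.5 and 6 h, 2062 between 6 and 12 h, 3165 between 12 and 24 h, 2648 between 24 and 48 h, 244 between 48 and 72 h and 6565 between 0.5 and 72 h. Among lists, 3 differences kept their call with an estimated correlation, namely the flavonoid list between 6 and 12 h with adjusted p = 0.0011, the heat shock list between 6 and 12 h with adjusted p = 0.00914, and the flavonoid list between 0.5 and 72 h with adjusted p = 0.0113. No group holds more than 2 libraries, so neither a test for an outlying library nor a count of other splits of the samples applies.

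Heat shock genes rose further between 6 and 12 h of high light. The list median was 0.58 at 6 h against 2.06 at 12 h, and the difference passed the list test. Steady leaf warming from the onset would need a delay to give this step, but it stays open, since 10 of 28 genes were already higher at 0.5 h and 11 at 6 h. Leaf warming that began after 6 h could also raise them and stays open, because only 1 leaf temperature is given for the series and none per time. A response to the light itself, without warming, stays open as a hypothesis.

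Root marker genes were lower from 24 h, 17 of 24 there against 7 at 0.5 h, 1 at 6 h and 9 at 12 h, and rose again in recovery. A smaller share of root tissue would lower the markers of every root part alike, and it is argued against as the whole cause. The 4 meristem and cap markers lay above the other 20 list genes on the log2 scale by 1.32 (SE 0.22) at 24 h, 1.59 (SE 0.38) at 48 h and 1.16 (SE 0.46) at 72 h, with means of -0.66 ± 0.40 and -1.81 ± 0.24 at 72 h. The SEs of these differences and of all marker means are over genes and do not measure the spread between libraries. By the test of single genes, 10 of 10 root hair, 6 of 7 endodermis and 0 of 4 meristem and cap genes were lower at 24 h. Library depth is argued against as well, since the root list median at 72 h was -1.5 with thinned counts. A change in root hair genes, with a mean of -2.29 ± 0.26 over 10 genes at 72 h, and endodermis genes, with -1.61 ± 0.46 over 7, may be biological, as a hypothesis. The remaining list genes at 72 h were SCR -0.31 ± 0.08 and PYK10 -1.01 ± 0.14, both lower, and NRT2.1 -0.84 ± 0.42, not past the test.

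In recovery 2489 genes still differed from 72 h growth light, and the recovery plants were 14 h older. A different phase of the day rhythm is argued against as the whole cause, since their recovery differences correlated at r = 0.07 with the growth light change from 0.5 and 24 h to 12 h, although 61.5% lay on the same side. Further, 12 of the 14 clock genes called have the sign of that change, so for clock genes the phase may matter. It may matter for antenna genes too, since 19 of 21 changed over growth light time. In growth light LHCB2.2 was at 480.8 and 451.8 CPM at 12 h, against 790.8 and 869.8 CPM at 24 h. The antenna list was not tested apart for phase. An unfinished return of the high light effect has what it needs, since the correlation with the 48 h effect was 0.63, with 77% of the genes on the same side. Age was not tested.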

How the results depend on the processing

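The tests on thinned counts, the extent of recovery and list tests without each library were chosen only after the result was seen, and the cause was not tested except where named. Of 921 calls of named genes, 167 were lost or changed sign in at least 1 setting, and the most in a setting that left out no library were 93 lost and 8 of changed sign, with all 12 growth light libraries as the control. Printed here are the results that moved. With no filter 680 effects differed between 48 and 72 h. With only the groups of the comparison, which leaves fewer libraries to estimate the spread, counts moved both ways. They fell to 2984 genes at 0.5 h, 4171 between 0.5 and 6 h and 1289 between 6 and 12 h. They rose to 1277 between 48 and 72 h and 4470 between recovery and growth light. Replicate spread was unequal, with a chi-square per gene between 2 libraries from 1.723 (growth light 72 h) to 11.796 (growth light 0.5 h). A spread shared over all groups can then be too small for some comparisons and too large for others, so counts are less comparable between times. With all 12 growth light libraries as the control 4411 genes still differed in recovery. DESeq2 called 6108 genes over time in growth light. With at least 2-fold required the counts fell by construction, to 1332, 1771, 1994, 3126, 2688 and 2863 at the 6 times, 1649, 412, 711, 558 and 66 for neighbouring differences, 2407 between 0.5 and 72 h, 2096 and 527 in recovery against high and growth light, and 1277 over growth light time. At all 6 times 231 genes then stayed, 140 higher and 91 lower, and 206 were called in both directions. The recovery median was 0.057 for genes higher at 24 h, and 0.184 and -0.448 for genes of at least 2-fold at 48 h. With an estimated correlation 29 of 219 list calls stayed, with rotation 194, with the replicate block 219 and with thinned counts 216. In all, rotation called 218 and thinned counts 223. With all 12 growth light libraries as the control the sign reversed for CP12-2 at 6 h (-0.15), GOX1 at 6 h (-0.00), MYB76 at 6 h (0.16), MYB29 at 6 h (0.28), AHA7 at 6 h (-0.28), CYCB2;2 at 12 h (-0.03), and FMOGS-OX1 (-0.21) and BCAT4 (-0.07) in recovery against growth light. That control ignores the change over time in growth light.

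Leaving out each library in turn leaves a lone sample, assumed to vary like the other groups. Effects that differed ran from 1134 to 2138 between 6 and 12 h, lowest without high light 12 h replicate 2, from 1618 to 2980 between 12 and 24 h, lowest without the same library, and from 1563 to 2434 between 24 and 48 h, lowest without high light 48 h replicate 1. They ran from 15, without high light 72 h replicate 1, to 105 between 48 and 72 h, and from 1039, without growth light 72 h replicate 2, to 1377 in recovery against growth light. The recovery median ran from 0.079 to 0.102 for genes higher at 48 h and from -0.168 to -0.116 for genes lower. All other counts over genes and lists stayed within 1.5 times, for example 3403 to 4282 genes at 0.5 h and 7554 to 7788 at 72 h. Replicate numbers do not pair the samples, since residuals of libraries with the same number correlated at -0.14 to 0.16 with a median of -0.01, and the replicate block gave 2429 genes in recovery against growth light. Depth limits the 72 h and recovery results, and with every library thinned to the smallest total, 4040 genes were called at 0.5 h, 9049 at 72 h and 2285 in recovery against growth light. DESeq2 gave no adjusted p for 6238 genes between 48 and 72 h, and 344 calls there. Among gene lists the larger side flipped in recovery against growth light for glucosinolate genes with DESeq2 factors and for starch genes with upper-quartile factors.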

Other observations

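The genes and families in this part and the test of root uptake genes in recovery were chosen only after the result was seen, while the tests of iron and sulfur genes not looked at before were set before their values were seen. Many genes that respond to low iron changed sides during high light. At 6 h the regulators bHLH38 (AT3G56970) -1.82 ± 0.24, BHLH100 (AT2G41240) -2.38 ± 0.23 and BHLH101 (AT5G04150) -3.09 ± 0.21 were lower and the storage and iron-sulfur genes FER1 (AT5G01600) 2.37 ± 0.30 and NEET 3.39 ± 0.39 higher. At 72 h bHLH38 2.70 ± 0.24, BHLH100 2.78 ± 0.22 and BHLH101 1.84 ± 0.18 were higher and FER4 (AT2G40300) -3.07 ± 0.28 and NEET -4.63 ± 0.60 lower. In recovery against growth light bHLH38 3.02 ± 0.24 and BHLH101 2.83 ± 0.18 were higher. FER1 -2.22 ± 0.38 and FER4 -1.86 ± 0.24 were lower, but FER3 -0.20 ± 0.09, adjusted p = 0.149, did not pass. Against high light 5 of 13 induced genes rose, 0 fell, and 2 of 8 storage-type genes rose, 3 fell. Of 3 storage genes not looked at before, AT3G25190 -0.72 ± 0.24 was lower at 6 h already, and the others did not pass there. Root uptake genes went the other way at 72 h, with IRT1 (AT4G19690) -3.27 ± 0.27 and FRO2 (AT1G01580) -2.25 ± 0.26.

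Genes that respond to low sulfur rose in high light, with ATSDI1 (AT5G48850) 3.22 ± 0.23, LSU1 (AT3G49580) 3.52 ± 0.23, LSU2 (AT5G24660) 1.86 ± 0.13 and SERAT3;2 (AT4G35640) 2.47 ± 0.16 at 72 h, and all 9 measured were lower in recovery against high light, among them ATSDI1 -4.05 ± 0.24, LSU1 -3.10 ± 0.22 and BGLU28 (AT2G44460) -4.74 ± 0.34. In recovery against growth light edgeR called 0 of the 9 higher and 3 lower, namely BGLU28 -2.66 ± 0.43, LSU3 (AT3G49570) -0.90 ± 0.25 and APR3 (AT4G21990) -0.28 ± 0.09.

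A low-iron state of the shoot is a hypothesis for late high light and recovery. Of 6 induced genes not looked at before, 5 were higher in recovery against growth light, as it needs, and of 3 storage genes of the vacuolar iron transporter family 2 were lower. A low-iron state of the whole seedling would raise root uptake genes, and of 7 not looked at before 0 were higher at 72 h and 6 were lower. At 72 h it stays open, since markers of root hairs (-2.29) and endodermis (-1.61) fell too, so fewer active root cells may hide a rise. At 6 h, 0 of all 9 uptake genes were higher and 8 lower, with few root markers lower. At 0.5 h, 7 root markers were lower, so the order is open. In recovery 6 of all 9 uptake genes rose against 72 h high light, as root hair markers did. Against growth light those markers averaged -0.37 ± 0.08 (SE over genes), with 1 of 10 called lower, and PYK10 was at -0.66 ± 0.14. A rise of most uptake genes beyond that shortfall is argued against, since edgeR called 0 of the 9 higher and 4 lower against growth light, 1 and 5 at an unadjusted p under 0.05 and 0 and 2 with DESeq2. A low-sulfur state is a hypothesis for late high light, and of 7 genes not looked at before 7 were higher at 72 h. Iron and sulfur contents were not measured here, so either state may be absent.

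Among 207 families of at least 12 genes with the same product name, 181 of 1656 list tests were called and none kept its call with an estimated correlation. Of 54 TIR-NBS-LRR disease resistance genes 28 were higher and 2 lower at 0.5 h, with adjusted p = 1.84e-12 and adjusted p = 0.0546 with an estimated correlation. At 12 h 3 were higher and 25 lower, with adjusted p = 0.0335 and adjusted p = 0.616 with an estimated correlation, and the difference between these times was not tested for the family. Of 25 xyloglucan endotransglucosylase genes 18 were lower and 4 higher at 72 h and 17 higher and 3 lower in recovery against high light, with adjusted p = 1.15e-06 and adjusted p = 0.27 with an estimated correlation at 72 h. Of 62 SAUR-like genes 38 were lower and 6 higher at 24 h, with adjusted p = 1.69e-05 and adjusted p = 0.494 with an estimated correlation. Of 30 NPH3 family genes 18 were lower and 1 higher at 72 h, with adjusted p = 9.61e-05 and adjusted p = 0.0546 with an estimated correlation.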
